A study of Anethum foeniculum with 6 samples.

How the data were processed

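The RNA of fennel leaves was sequenced from plants grown under ambient sunlight (control) and from plants given ambient sunlight plus narrow-wavelength red light from light-emitting diodes (red), with 3 libraries in each group. Per the labels' protocols, total RNA was taken from about 50 mg of leaf, treated with DNase and sequenced by a service company as paired 150 bp reads on an Illumina NovaSeq instrument. The labels call the libraries biological replicates, without saying whether a library held 1 plant or several.

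The authors deposited 1 table of counts with 127290 rows and 6 columns, 1 column per library. Per the file headers, each column is named for its library, and each column was assigned through the library name in the sample labels. The row identifiers follow the gene naming of the Trinity de novo assembler, which builds transcripts from the reads without a reference genome. A row is therefore an assembled gene, and rows that share a DN number belong to the same assembled cluster (104349 clusters). The assembler's version, the aligner, the counting program and whether rows were filtered are not given in the sources used here. All values were whole numbers and were not scaled to a common total, so they were treated as raw counts. They may still be rounded estimates, since 7 sets of rows in the same subcluster held identical non-zero counts in every library. The table pairs no row with a gene name, a sequence or a position, and no reference was used. Gene functions, coordinates, transcript length and base composition were therefore not analysed here, and the pathway and cell type lists drawn up beforehand could not be applied.

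Total counts per library ranged from 18040162 to 22992137. Of the rows, 4404 were at 0 in all libraries and 25102 had a count in all 6. A limit of 3 counts corresponds to 0.130 to 0.166 CPM (counts scaled to the library total), depending on the library, and covers counting error only.

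The main test was edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3) on all 6 libraries, with the light treatment as the only term. Rows were filtered with filterByExpr, which left 36013 genes, and libraries were scaled by the trimmed mean of M-values (TMM). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. DESeq2 (1.42.0) and limma-voom (limma 3.58.1) were run as alternatives, as were other normalizations and filters, a replicate block and the removal of each library in turn. The main design and those alternatives were fixed before the data were examined. Sums over assembled clusters, filters on mean CPM, filters that ask for 1 CPM or 10 counts in all 6 libraries, a robust prior and DESeq2 on the genes of the main test were added afterwards.

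A description that does not depend on a variance model was also added after seeing the data. A gene was called separated when its log2 CPM (prior count 2) in all 3 red libraries lay above, or in all 3 lay below, its values in the 3 control libraries. Chance gives 10% of genes this property with 3 against 3 libraries. Separated genes with a mean of at least 5 CPM and at least a 4-fold difference of group means of log2 CPM were counted in the treatment split and in the 9 other splits of the libraries into 2 groups of 3. Measures with 1 value per library were compared by exact two-sided permutation tests, for which the smallest possible p with 3 against 3 libraries is 0.1.

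The rule set beforehand for genes to be named required an adjusted p under 0.05, which no gene reached in the main test. The 2 higher and the 2 lower genes with the smallest unadjusted p were named instead. They were chosen after their values were seen, from separated genes with a mean of at least 5 CPM and more than 3 counts in every library. Replicate numbers were checked for pairing. The correlation between same-numbered control and red libraries, in their deviations from the group means, was -0.06, -0.02 and -0.05 for replicates 1, 2 and 3, so the numbers were not treated as pairs.

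The scripts were tested on simulated data drawn from the means and library sizes of the 36013 genes, with 100 genes changed by 4-fold and 100 by 16-fold between red and control. With the dispersion of each gene as estimated from the data, edgeR recovered 15% of the 4-fold and 75% of the 16-fold changes with 3 false calls. DESeq2 recovered 68% and 98% with 253 false calls. Separation in the right direction, at any fold, was found for 84% and 100%. Of the unchanged genes, 1104 were separated with at least a 4-fold difference, and 85 of these had a mean of at least 5 CPM. With a dispersion of 0.05 for every gene, both tools recovered 100% at both fold sizes, with 10 and 23 false calls, and 0 unchanged genes were separated by at least 4-fold. Genes were drawn independently of each other in these simulations. In the real libraries, 47 higher and 26 lower separated genes with at least 5 CPM differed by at least 16-fold, and edgeR's main test called none. The simulated recovery by edgeR may therefore overstate what its test finds in the real data.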

Results

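Leaf transcriptomes of hydroponic fennel, an aromatic herb of the carrot family, were compared between 3 control libraries from plants under ambient sunlight and 3 libraries from plants given supplemental red light. The design asks how red light added to sunlight alters leaf gene expression. Total counts were 18040162, 18951242 and 22992137 in control replicates 1 to 3 and 22673552, 19692790 and 18839959 in red replicates 1 to 3. Depth overlapped between the groups (exact permutation p = 0.8, two-sided, n = 3 each). Genes are given by their assembly identifiers, because the table pairs none of them with a name, and their functions were not analysed here.

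Control leaves resembled each other more closely than red leaves did. Across the 36013 tested genes, Pearson's r of log2 CPM between 2 libraries averaged 0.80 within control (0.79 to 0.81), 0.76 within red (0.74 to 0.78) and 0.76 between the groups (0.73 to 0.79). These correlations are across genes, which are not independent replicates. The first principal component held 28.3% of the variance and set red replicates 1 and 2 apart from the controls, whereas red replicate 3 lay beside the controls. On the second, with 20.9%, red replicates 2 and 3 lay at 127 and 140 and red replicate 1 at -114. The controls lay there at 26.6, -28.2 and -151. Mean r of red replicate 3 was 0.79 with the controls and 0.76 with the other red libraries. The mean distance between libraries of different groups exceeded that within groups by 18.6 log2 units (381 against 363), the largest value among the 10 splits of the libraries into 2 groups of 3. The highest of the other splits gave 12.9. Leaving out 1 library moved the difference to 8.94, 8.23 and 6.81 without control replicates 1, 2 and 3, and to 43.9 without red replicate 3. The difference was smaller than the SD of the within-group distances, 27.1.

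**Figure D1:**
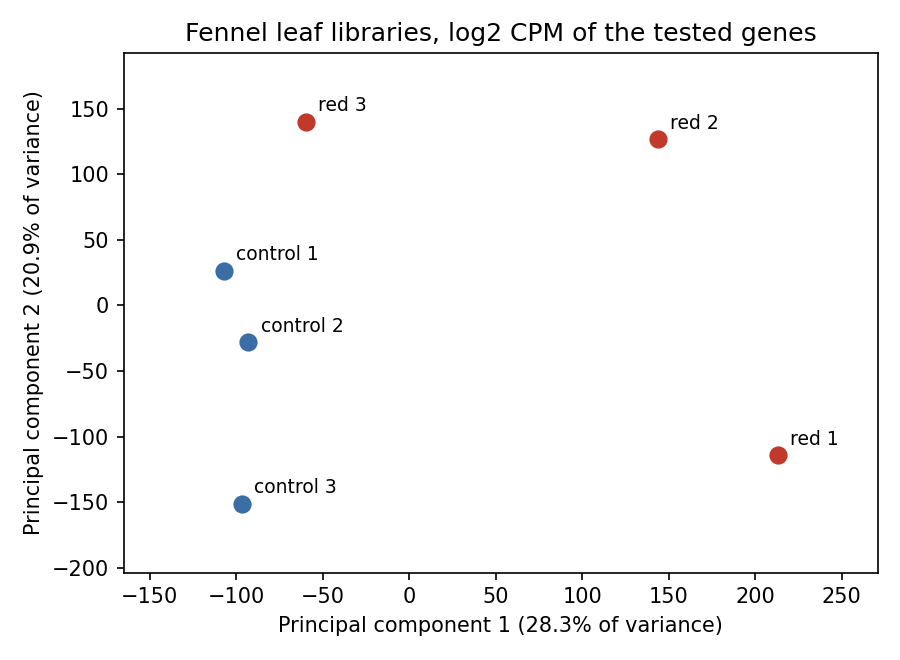
Position of the 6 libraries on the first 2 principal components of log2 CPM over the tested genes (x axis, component 1 with 28.3% of the variance; y axis, component 2 with 20.9%), 1 point per library, blue for control and red for red light. On component 1, red replicates 1 and 2 lie to the right, and red replicate 3 lies on the side of the 3 controls. On component 2, red replicates 2 and 3 lie above the 3 controls.

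Under red light, 250 genes stood at least 4-fold above their control level and 111 at least 4-fold below it, with all 3 red libraries on one side of all 3 controls and a mean of at least 5 CPM. Among those with a count in all 6 libraries (225 of the 250 higher and 86 of the 111 lower genes), the median difference was 6.49-fold and 6.03-fold. Together the 250 higher genes took 0.897% ± 0.25 of all counts in control leaves and 5.67% ± 1.58 in red leaves (SD, n = 3). The 111 lower genes took 1.28% ± 0.0981 in control and 0.214% ± 0.158 in red. Both sets were chosen on these libraries, so their sums are not independent evidence of a direction. Chance separates 10% of genes in this way before the fold and abundance limits. The treatment split gave 361 such genes, and the 9 other splits of the libraries gave 31 to 165. Without red replicate 1 the number was 358, and without red replicate 3 it was 869, where chance separates 20% of genes with 2 libraries against 3.

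**Figure D2:**
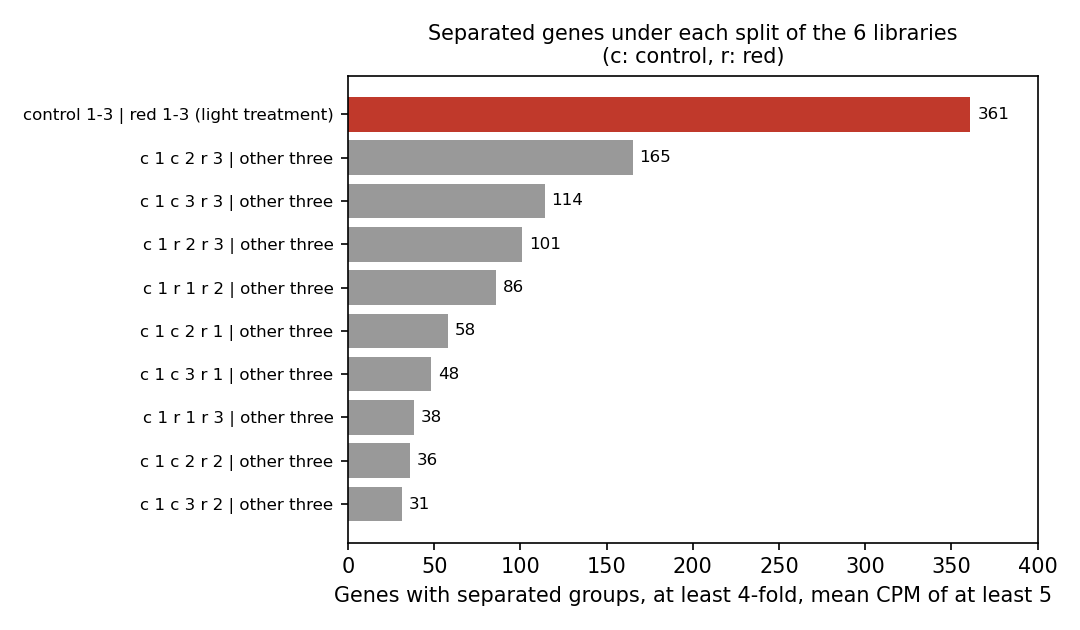
Number of genes (x axis) with separated groups, at least a 4-fold difference and a mean of at least 5 CPM, for each of the 10 ways to split the 6 libraries into 2 groups of 3 (y axis). The split by light treatment (red bar) gives 361 genes, against 31 to 165 for the other splits (grey bars).

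No gene passed the main test: edgeR's quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p under 0.05, and therefore 0 with at least a 2-fold change. The smallest adjusted p was 0.18. At an unadjusted p under 0.05 it listed 3172 genes (1815 higher and 1357 lower in red), where chance gives 1801. The other splits of the libraries gave 784 to 2637 such genes. Without red replicate 3, where the filter run anew left 52573 genes, the same edgeR test called 26 genes higher and 17 lower. Limma-voom also called 0 genes, with 3646 at an unadjusted p under 0.05. DESeq2 called 949 genes higher and 687 lower among the same genes, and 638 of these 1636 calls had a count of 0 in at least 3 libraries. On the genes of the main test, DESeq2 called 4503 without red replicate 3, 980 without control replicate 2 and 933 without control replicate 3. The majority of its calls turned with the library left out: 40.3% to 45.1% were higher without any 1 red library, and 78.8% to 79.5% without any 1 control. Of the 946 DESeq2 calls with counts in all 6 libraries, 673 were higher and 273 lower. The same edgeR test without a filter on low counts, over 122886 rows, called 214 genes higher and 40 lower, of which 225 were also DESeq2 calls. The biological coefficient of variation between libraries of a group was 95.5%.

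Among genes with a count above 3 in every library, TRINITY_DN2239_c0_g4 had the smallest p of the higher genes. It averaged 2.32 ± 0.882 CPM in control and 52.4 ± 14.0 CPM in red (SD, n = 3), a log2 fold change of 4.50 with a standard error of 0.40. TRINITY_DN7808_c0_g2, an abundant transcript under red light, stood at 72.3 ± 7.65 CPM in control and 1018 ± 380 CPM in red, a log2 fold change of 3.82 with a standard error of 0.36. Of the lower genes, TRINITY_DN7845_c0_g1 averaged 71.6 ± 15.1 CPM in control and 5.74 ± 2.34 CPM in red (log2 fold change -3.64, standard error 0.36). TRINITY_DN2320_c0_g1 averaged 32.0 ± 9.04 CPM in control and 5.28 ± 0.583 CPM in red (log2 fold change -2.60, standard error 0.28). Each of the 4 had an edgeR quasi-likelihood adjusted p of 0.18 and did not pass. DESeq2 called all 4, with adjusted p from 2.9e-24 for TRINITY_DN7808_c0_g2 to 3.6e-13 for TRINITY_DN2320_c0_g1, and so did edgeR without a filter, with adjusted p from 0.00011 to 0.0040. Over all alternatives run, adjusted p of these genes reached down to 4.9e-28 (TRINITY_DN7808_c0_g2, DESeq2 over all rows) and up to 0.67 (a replicate block). The assembled cluster of TRINITY_DN2239_c0_g4 held 3 other tested genes, all higher in red, 1 of them at an unadjusted p under 0.05. The 1 other tested gene in the cluster of TRINITY_DN7808_c0_g2 was also higher in red at an unadjusted p under 0.05. Members of a cluster may share reads, so these genes are not independent support. The clusters of the 2 lower genes held 0 other tested genes.

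**Figure D3:**
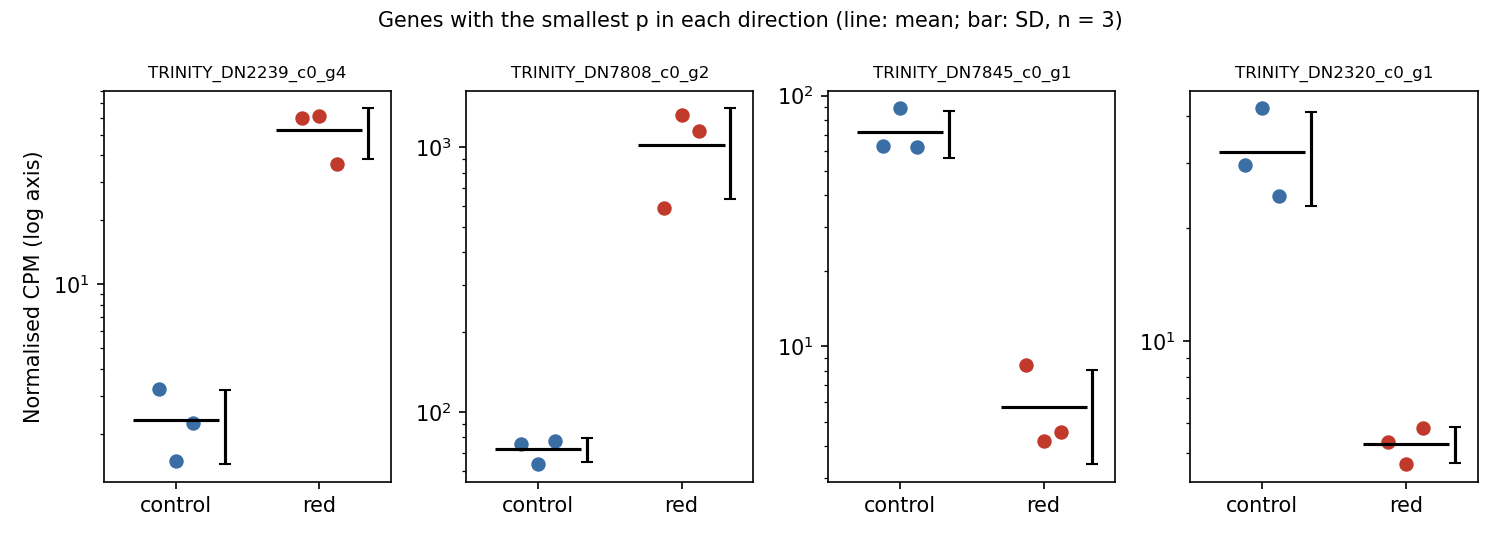
Normalised CPM (y axis, log scale, a separate scale in each panel) of the 4 named genes in control and red libraries (x axis), with 1 point per library, the group mean as a line and the SD as a bar (n = 3). The red libraries lie above the controls in the 2 left panels and below them in the 2 right panels.

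Well expressed and scarce genes differed in how often they stood apart between the light treatments, and the order depended on the measure. Of the 2924 genes with a mean of at least 50 CPM, 16.9% had an unadjusted edgeR p under 0.05 (314 higher, 180 lower), where chance gives 5%. The share was 13.8% of the 11098 genes with 5 to 50 CPM (932 higher, 603 lower) and 5.2% of the 21991 genes under 5 CPM (569 higher, 574 lower). Separated genes made up 24.6%, 20.3% and 13.8% of these 3 classes, against 10% by chance. Over all tested genes, the separated share was 16.7% in the treatment split and ranged from 6.74% to 14.7% in the other splits. The other splits were not broken down by class, so no class's share, by p or by separation, can be read as an excess over them. Separation with at least a 4-fold difference was found for 3.11% of the genes at or above 50 CPM (65 higher, 26 lower), 2.43% at 5 to 50 CPM (185 and 85) and 7.30% under 5 CPM (712 and 893). Simulated unchanged genes gave 1019 such genes under 5 CPM and 85 at or above 5 CPM. When only genes with a mean of at least 50 CPM were tested, edgeR called 12 higher and 2 lower, and DESeq2 also called all 14.

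The most abundant transcripts took a larger share of counts in red leaves than in control leaves. The 10 most abundant genes of each library took 8.50% ± 0.460 of counts in control and 11.1% ± 0.567 in red, and the top 100 took 24.5% ± 0.682 and 28.3% ± 1.48 (SD, n = 3). All red libraries lay above all controls for both measures (exact permutation p = 0.1, two-sided, the smallest this design allows). For the top 1000 genes the shares were 57.1% ± 0.787 and 57.9% ± 3.80 (exact permutation p = 0.9). Red replicate 1 had 53.5% there, and without it the red mean was 60.1%, where the highest control had 57.7%. A single gene made the largest gain, from 0.170% ± 0.0680 of counts in control to 1.35% ± 0.329 in red (log2 fold change 3.13, standard error 0.42, edgeR adjusted p = 0.27, DESeq2 adjusted p = 5.3e-13). It was singled out after its values were seen. The most abundant gene took 1.93% ± 0.678 in control and 2.96% ± 0.295 in red (edgeR adjusted p = 0.62). The second took 1.89% ± 0.156 in control and 1.61% ± 0.493 in red, where the groups overlapped (edgeR adjusted p = 0.98).

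Some genes were detected under one light treatment only. In all, 264 genes had at least 10 counts in each red library and none in any control, and 435 had at least 10 counts in each control and none in any red library. Together the red-only genes took 0.0555% of counts in red libraries, and the control-only genes 0.0829% in controls. Of these genes, 3 red-only and 2 control-only ones had a mean of at least 5 CPM over all libraries, and the highest group means were 19.8 and 63.9 CPM. The total of 699 was close to that of arbitrary splits, since the 9 other splits of the libraries gave 500 to 619. Of the 243 red-only and 402 control-only genes tested, edgeR called 0 and 0, had 243 and 402 at an unadjusted p under 0.05, and DESeq2 called 243 and 395. Small p values in these genes follow from the way they were chosen. With 1 library left out, the total ranged from 1755 (without red replicate 1) to 5518 (without red replicate 2). The larger set turned from control-only to red-only without any 1 red library (1130 against 625, 4854 against 664 and 1393 against 742 without red replicates 1, 2 and 3), where only 2 red libraries had to meet the limit. The count without red replicate 2 takes in the 4557 genes detected in red replicates 1 and 3 alone.

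Red replicate 1 held more detected genes than any other library. Genes with at least 1 count numbered 54384 ± 2747 in control and 59490 ± 10817 in red (SD, n = 3; exact permutation p = 0.7, two-sided). Red replicate 1 had 71504, while red replicates 2 and 3 had 50525 and 56442, and the controls 52757 to 57556. Without it, the red mean was 53484, below that of the controls. Thinning all libraries to the smallest total left 71431 genes in red replicate 1 and 50507 to 57547 in the others. In red replicate 1, 21054 genes had at least 10 counts and none in the other 5 libraries, holding 7.88% of its counts (95% Clopper-Pearson interval 7.87 to 7.89, for counting error only). The other libraries each held 4527 to 6616 such genes.

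**Figure D4:**
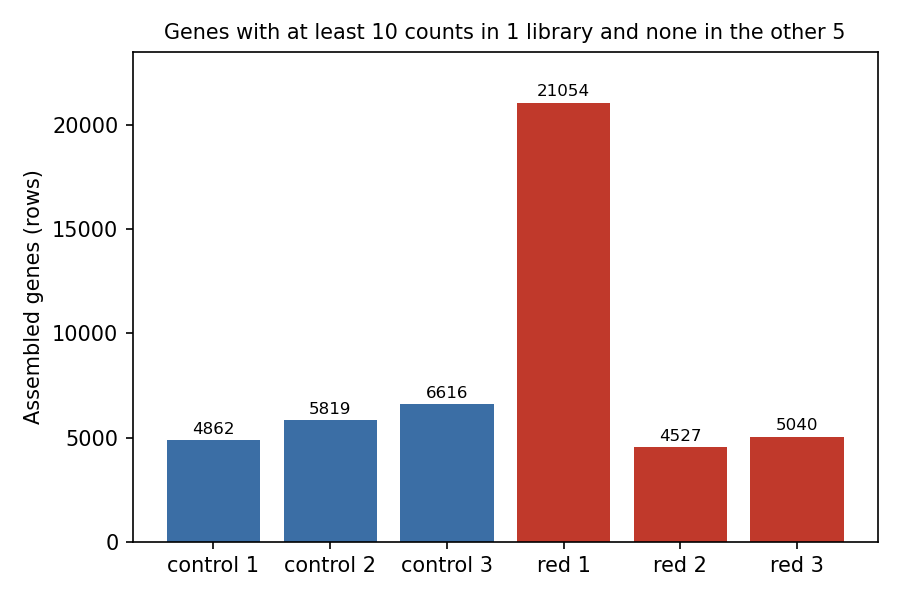
Number of assembled genes (y axis) with at least 10 counts in 1 library and none in the other 5, for each library (x axis), blue for control and red for red light. Red replicate 1 has 21054 such genes, and the other libraries have 4527 to 6616.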

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

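All tests in this part except that of a swap of red replicate 3 with control replicate 3 were chosen after the result was seen. Those of a common light response and of a control label replaced earlier tests that had not decided, and the gene set for the swap was chosen after no gene passed edgeR's test.

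In red replicate 1, 21054 genes had at least 10 counts with none elsewhere, against at most 6616 in a control library, a signal outside the genes tested. Greater depth is argued against, since control replicate 3 had more counts in total (22992137 against 22673552) and 6616 such genes. After thinning to the smallest total, 21009 such genes were left, where the highest other library had 6589. Thinning alone could remove few of them, because their median in red replicate 1 was 72 counts. Whether a light response common to the 3 red libraries was their source could not be tested on these 21054 genes. They were chosen for having no count in the other 5 libraries. Their absence from red replicates 2 and 3 (totals of 19692790 and 18839959) follows from that choice. The test of shares did not decide: of the 29272 genes with at least 10 counts in red replicate 1 and none in the controls, 5.32% had a count in red replicate 2 and 24.0% in red replicate 3, but 21054 of them are the genes chosen for having no count there. A second source of RNA or DNA in this library was not decided either: of its genes in clusters of several rows, 49.3% lay in clusters with no count in any other library (112 of 1021 in the highest other library), but such a share grows with the number of genes seen in 1 library alone. A response of that 1 sample to its surroundings was not tested.

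Red replicates 1 and 3 shared 4557 genes with at least 10 counts in both and none in the other 4 libraries, against at most 1619 for a pair of controls. The same second source in both at 1 constant ratio is argued against. Of the 173 genes with at least 300 counts in red replicate 1 and none in the controls or red replicate 2, 40.5% (95% Clopper-Pearson interval 33.1 to 48.2) had a count in red replicate 3, although their median ratio, where present, was 5.96. Several sources, or 1 source differing in make-up between the libraries, may still account for them, as may light acting on these plants unequally, and none of these was tested. DESeq2 over all rows called 1603 genes, of which 525 were detected in red replicates 1 and 3 alone.

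Red replicate 3 lay near the controls on the first principal component. A control library under that label is argued against by the size of 1 gap, without being excluded. With red replicates 1 and 2, red replicate 3 gave 361 separated genes of at least 4-fold. Each control in its place gave 86 to 165. The rank alone decides little, since 1 of the 4 libraries must come highest, and the SD of the controls (40.1) rests on 3 values. Mean r of red replicate 3 was higher with the controls (0.79) than with the other red libraries (0.76). A swap with control replicate 3 is argued against too: on a scale from 0 (control replicates 1 and 2) to 1 (red replicates 1 and 2), control replicate 3 had a median position of 0.0368 and red replicate 3 of 0.34, over the 100 genes with the smallest p between those 4 libraries. Over the 43 genes called without red replicate 3 its median position was 0.33, which lay between the bounds of the earlier test, and it lay beyond the control range in 35. Both gene sets were chosen for a difference between red replicates 1 and 2 and controls. A red library left out of that choice would tend to fall short of 1 even with a full response. A smaller response to red light, or a partial mixture with a control, stays open and was not tested.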

How the results depend on the processing

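Chosen after seeing the data were the counts of separated genes, DESeq2 on the genes of the main test, the robust prior, the mean CPM minimums, the filters over all 6 libraries and the sums per subcluster or cluster. The count of 0 genes higher and 0 lower held with DESeq2's size factors, library size alone (which shifted the median log2 fold change to -0.11), a minimum of 1 CPM in 3 libraries, limma-voom, a robust prior, 1 CPM or 10 counts in all 6 libraries, mean CPM minimums of 1, 5 and 10, and sums per assembled subcluster or cluster. Replicate numbers did not pair the libraries, and the fit with a replicate block also called 0 genes, with 1912 at an unadjusted p under 0.05. Without a filter, edgeR called 214 higher and 40 lower (254 by at least 2-fold), and with a mean CPM of at least 50 it called 12 and 2 (14). DESeq2 called 949 higher and 687 lower on the same genes (1453 by at least 2-fold), and 1212 and 391 with its own filtering (1601), which moved the share of higher calls from 58.0% to 75.6%. Of the 1603 calls with its own filtering, 904 were detected in 2 libraries only. The 525 of them in red replicates 1 and 3 alone count as higher by necessity. Leaving out 1 library gave 0 to 26 higher and 0 to 17 lower genes (0 to 43 by at least 2-fold), with the calls only without red replicate 3. In these edgeR fits the filter was run anew and left 52030 to 55501 genes. DESeq2's 1636 calls ranged from 933 (without control replicate 3) to 4503 (without red replicate 3), and were 980 without control replicate 2, with 40.3% to 45.1% higher when a red library was left out and 78.8% to 79.5% when a control was. Separated genes of at least 4-fold numbered 1153 with a mean CPM of at least 1 and 236 with at least 10, and 344 to 869 with 1 library left out (highest without red replicate 3), where chance separates 20% of genes instead of 10%. Genes detected in one group only numbered 1145 at a minimum of 5 counts and 245 at 20, and 1755 to 5518 with 1 library left out, highest without red replicate 2, which takes in the 4557 genes detected in red replicates 1 and 3 alone. The excess of detected genes in red, 5106, ranged from -900.5 without red replicate 1 to 9589 without red replicate 2. The red excess in the share of the most abundant genes was 3.77 percentage points for 100 genes and 0.787 for 1000. The 4 named genes kept their direction under every setting that tested them. This largely follows from choosing them among separated genes and is not independent support. The distance between groups stayed above that within groups, by 6.81 (without control replicate 3) to 43.9 (without red replicate 3) log2 units with 1 library left out. The causes were not tested. Genes near the limit of 3 counts, 0.130 to 0.166 CPM, could not be compared reliably. Sums per isoform and the pathway lists were not run, because the rows are genes and carry no names.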

Other observations

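The counts over splits, and the margin asked of the test of cluster members, were chosen after the result was seen, whereas the test of sibling rows was not.

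Responses of related transcripts were compared within assembled clusters, which group sequences that share reads or stretches of sequence. Over 1985 pairs of genes from the same cluster, each with a mean of at least 5 CPM, Pearson's r of the log2 fold changes was 0.24 in the treatment split (across genes, which are not independent) and 0.0746 to 0.22 in the other 9 splits. That members of a cluster share a response to red light is a hypothesis that this small margin does not separate from shared reads, which would act in every split.

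Genes detected under one light treatment only may be alleles or near-identical contigs among which reads move. The other rows of their clusters, summed, would then shift the opposite way. Their median log2 ratio of red over control was -0.07 for 81 clusters with control-only genes and 0.02 for 77 with red-only genes, a difference of -0.0884 (permutation p = 0.37 from 100000 resamples, two-sided), so the test did not decide. Clusters, not libraries, were resampled, and clusters measured in the same libraries are not independent.

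With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The treatment split gave the largest count of genes detected in one group only (699, highest other 619; 1 of 10 splits as large), of DESeq2 calls (1636, highest other 1039; 1 of 10) and of separated genes of at least 4-fold (361, highest other 165; 1 of 10). The main edgeR test called 0 in the real and in each other split (10 of 10 as large). At an unadjusted p under 0.05 it listed 3172 genes (highest other 2637; 1 of 10), and without a filter it called 254 (highest other 11; 1 of 10). Leaving out red replicate 3, the treatment split gave 43 edgeR calls among 52573 genes filtered anew. Among the genes of the main test it gave 4503 DESeq2 calls and 869 separated genes of at least 4-fold. Chance then separates 20% of genes, and no other split without that library was run for comparison. DESeq2 calls with a count of 0 in at least 3 libraries numbered 638 in the real split and 396 to 559 in the others, while its other calls numbered 998 and 58 to 480.

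Low counts were rare in the table. Of 341623 values above 0, 1134 (0.332%) were a count of 1 and 6794 (1.99%) a count of 6, the most frequent of the values from 1 to 12, and the median was 43.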
